A study of Drosophila melanogaster with 3 samples.

How the data were processed

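Genomic DNA from embryos carrying a transgene for Dam alone or for the DamCiRep fusion under UAS control was compared on 3 two-colour arrays. Per the labels, eggs were collected for 2 h and aged for 4 h at 25 °C, while the extraction text gives an age of 2 to 6 h. On replicates 1 and 3 the Dam alone DNA carried Cy3 and the DamCiRep DNA Cy5, and on replicate 2 the dyes were exchanged. The arrays form 1 group, each holding both kinds of DNA, and each ratio was tested against 0.

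Scanner intensity per spot was extracted by the authors' provider with NimbleScan 2.3.78, per the file headers, and it is a linear value with no background correction stated there. The deposited value table holds log2 ratios of Cy5 over Cy3 that the authors made with limma in R 2.7.1, per the submitters' processing notes. Set against the scanner files, its columns for replicates 2 and 3 equalled the log2 ratio of the scans less a smooth trend on intensity, as a loess leaves it, with a remaining SD of 0.0008 and 0.0009. Its direction was Cy5 over Cy3 on both, not turned for the dyes. The column medians were -0.004, 0.010 and -0.002 for replicates 1, 2 and 3. How the loess was set is not given in the sources used here.

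The Cy5 file of replicate 1 was byte for byte that of replicate 3, with 385000 of 385000 values equal. The table column of replicate 1 could not be rebuilt from it: the SD around the trend was 0.476 and r with the log2 ratio of the scans was 0.633, against 0.921 and 0.906 for replicates 2 and 3. Its scale and direction were therefore taken to be those of the other columns. The plan fixed before the data were examined was to use median-centred scanner signals. Because that could not be done for replicate 1, the authors' table became the main source for all 3 arrays, and scanner signals of replicates 2 and 3 an alternative. Loess in the table removes any true trend of the ratio on intensity.

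The array had 385000 spots: 377566 tiled probes on 2L, 2R, 3L, 3R, 4 and X, 1434 random control probes and 6000 repeat spots, which were averaged with their tiled probe. A stretch of 1 Mb on 2L, from 13500001 to 14500000, held 13192 of the probes. Ratios were turned to DamCiRep over Dam alone by the dyes in the labels and centred on the median of the tiled probes of each array. Probes were averaged in fixed windows of 2 kb with at least 3 probes, with a median of 7 probes per window. The mean of the 3 arrays was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), two-sided, with Benjamini-Hochberg adjustment at 0.05. The prior had 9.23 degrees of freedom for windows and 5.57 for probes. Domains of 50 kb needed at least 50 probes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

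The window test was tested on simulated data for this comparison, with the 56753 windows and their moderated spread. With 200 changed windows it recovered 34% of shifts of 0.5 and 100% of shifts of 1, 1.5 and 2 on the log2 scale, with 9 false calls. With 10000 changed windows it recovered 82.4% of shifts of 0.5 and 99.96% of shifts of 1, with 438 false calls. The simulation draws arrays as independent.

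By the rule fixed before the data were examined, the text names the 10 highest and 5 lowest called windows by mean ratio, skipping any within 20 kb of one already taken. Agreement of arrays was described by Pearson's r. Arms were compared by the mean ratio per array with an exact sign-flip test, and by Fisher's exact test of called windows. Alternatives covered a dye term, the source of the values, loess, quantile normalization of mean intensity, normexp background correction with an offset of 50, scaling of the arrays, removal of the dimmest 10% of probes, medians, robust fits with an intensity trend, an adjusted p of 0.01, windows of 1 and 5 kb, at least 5 probes, combined probe p-values and each replicate left out. Tests of genes, gene lists, the exons of ci and the Ci motif needed an annotation or sequence of the array's own build, which was not used here. A gene table of another release was read only to compare lengths: 868 of its genes on 2R and 564 on 3R end beyond the last probe.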

Results

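The series addressed where the repressor form of cubitus interruptus (Ci) sits on the genome of Drosophila melanogaster embryos at stages 10 to 11. Ci is the zinc finger transcription factor at the end of the Hedgehog pathway, and in cells without Hedgehog signal it is processed to a shorter protein that represses its targets. The assay was DamID, in which a bacterial adenine methyltransferase (Dam) is fused to a chromatin protein and leaves methyl marks on GATC sites near the places the fusion visits. DNA methylated by the fusion with the Ci repressor form (DamCiRep) was set against DNA methylated by Dam alone, which records how open and reachable each site is without the fusion partner. Both were hybridised to 3 two-colour tiling arrays, replicates 1, 2 and 3, of 377566 tiled probes each, with probes of 60 bases about 300 bp apart. The dyes were exchanged on replicate 2. Ratios below are DamCiRep over Dam alone on the log2 scale, so a positive value stands for more methylation by the fusion and a negative one for more methylation by Dam alone. Positions are those of the array design, counted from 1, and its genome build was not given in the sources used here. No gene is therefore named for any position.

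The tiled probes gave signals well above the 1434 random control probes on every scan used. The median Dam alone signal was 1617, 1605 and 1141 on replicates 1, 2 and 3, against 185, 180 and 305 for the random probes, and 82.5%, 84.9% and 77.7% of the tiled probes lay above the 95th percentile of the random probes. The median DamCiRep signal was 860 on replicate 2 and 801 on replicate 3, and 77.1% and 73.1% of the tiled probes lay above that percentile. The Cy5 scan deposited for replicate 1 held the same values at all 385000 spots as the Cy5 scan of replicate 3, so that the DamCiRep signal of replicate 1 was not used and the ratios of all 3 arrays were taken from the authors' processed values. From spots printed more than once, the SD of the ratio of a single spot was 0.21, 0.22 and 0.24 within replicates 1, 2 and 3. The number of arrays limits the precision, and p-values measure only the spread between these 3 arrays, since nothing in the labels says that each came from a separate collection of embryos. In limma the spread of each window is also drawn towards that of all windows. A window with a wide SD can therefore have a smaller standard error than its own 3 arrays would give.

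The first comparison was of the arrays with each other, which also checks the dyes in the labels. Once turned to DamCiRep over Dam alone, all pairs correlated positively, although replicate 2 carried the dyes the other way round. Across 2 kb windows, Pearson's r was 0.68 between replicates 1 and 2, 0.52 between 1 and 3 and 0.53 between 2 and 3. Across single probes it was 0.59, 0.43 and 0.43 for the same pairs, and across 50 kb domains 0.81, 0.60 and 0.63. Windows, probes and domains are not independent replicates, so these values carry no p. Among the random control probes r was 0.05 between replicates 1 and 2 and 0.01 between 2 and 3, but 0.28 between replicates 1 and 3, which share their dye orientation. All 3 arrays gave 1 sign to 55.5% of the windows, against 25% for independent arrays, a value that is too low if arrays share Dam alone DNA.

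The main comparison asked where the fusion methylated more, or less, than Dam alone. DamCiRep methylation was higher in 5493 and lower in 5195 of 56753 windows of 2 kb, together 18.8% of the windows tested. The changes were mostly small: the median ratio was 0.55 among the windows called higher and -0.56 among those called lower, and the median SD of a window over the 3 arrays was 0.20. With the directions as labelled, large differences lay mainly on the Dam alone side. Only 31 windows were more than 2-fold higher with DamCiRep, and 278 were more than 2-fold lower; an exchange of the DNA sources in the labels of all 3 arrays, which these data do not exclude, would turn both counts round. Calls were made with limma and Benjamini-Hochberg adjustment at 0.05. The counts were 3148 higher and 2997 lower without replicate 1, 1309 and 1875 without replicate 2, and 7453 and 7061 without replicate 3. With replicates 1 and 2, whose Dam alone signals were nearly alike, averaged into 1, they were 4199 and 3962. If these arrays share Dam alone DNA, the spread in the main fit is too small. With the scanner signals of replicates 2 and 3 centred on the median, and no correction for intensity, the split of calls was 66.2% higher, against 51.4% in the main fit and 51.2% in the main values without replicate 1.

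The 10 highest windows, taken at least 20 kb apart, lay on 4 of the 6 arms tiled. The highest was on X at 15514001 to 15516000, where the ratio was 1.26 ± 0.44 (SD, n = 3), or 2.40-fold, with a limma adjusted p of 0.00217. On 3L the window at 4626001 to 4628000 had a ratio of 1.25 ± 0.26 (SD, n = 3). Another on 3L, at 14938001 to 14940000, had the tightest spread of the 10, with a ratio of 1.20 ± 0.11 (SD, n = 3) and a limma adjusted p of 0.000972. On 2L, the windows from 15532001, 3820001 and 15730001 had ratios of 1.18 ± 0.62, 1.15 ± 0.28 and 1.10 ± 0.28 (SD, n = 3). On X, the window from 20388001 had 1.15 ± 0.38, and on 3L that from 11140001 had 1.12 ± 0.16 (SD, n = 3). On 3R, the windows from 16672001 and 16576001 had 1.09 ± 0.29 and 1.08 ± 0.32 (SD, n = 3). All 10 were higher on all 3 arrays, and the widest spread was that of the 2L window from 15532001, whose replicates ranged from 0.54 to 1.77. With the median-centred scanner signals of replicates 2 and 3, ratios were larger in all 10 but the X window from 20388001, which had 0.87. The highest was then the 3L window from 14938001, with 1.77, against 1.27 for the authors' values of these arrays.

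In the main fit the 5 lowest windows departed further from 0. With the median-centred scanner signals of replicates 2 and 3 this did not hold for the X window among them. The lowest was on 3R at 26308001 to 26310000, with a ratio of -2.96 ± 0.63 (SD, n = 3), 7.76-fold more methylation with Dam alone, and a limma adjusted p of 0.000139. Its DamCiRep signal was 2.03 log2 units over the random probes, against 5.53 for Dam alone. On chromosome 4, the window at 70001 to 72000 had a ratio of -2.81 ± 0.96 (SD, n = 3), or 7.01-fold. Its limma adjusted p of 0.00054 rests on a moderated standard error of 0.26. Dam alone signals there were close to the highest that the scans recorded, so the size of this ratio is uncertain. It was -2.05 with the median-centred scanner signals of replicates 2 and 3, against -2.69 for the authors' values of these arrays. Without replicate 2 the authors' values gave -3.33, below the -2.85 of the 3R window. On X, the window at 2646001 to 2648000 had -2.37 ± 0.90 (SD, n = 3), with part of its probes near the same ceiling. With those scanner signals it had -1.58, against -1.99 for the authors' values of replicates 2 and 3. These last windows overlapped the only places where the ratio stayed beyond 2-fold on every array over 11 probes in a row, and replicate 2 gave them the ratios nearest to 0, -1.76 and -1.37. The windows on 2R from 18838001 and on 3L from 14636001 had -2.08 ± 0.12 and -2.06 ± 0.16 (SD, n = 3), with nearly equal values on the 3 arrays. All 5 were lower on all 3 arrays.

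**Figure D1:**
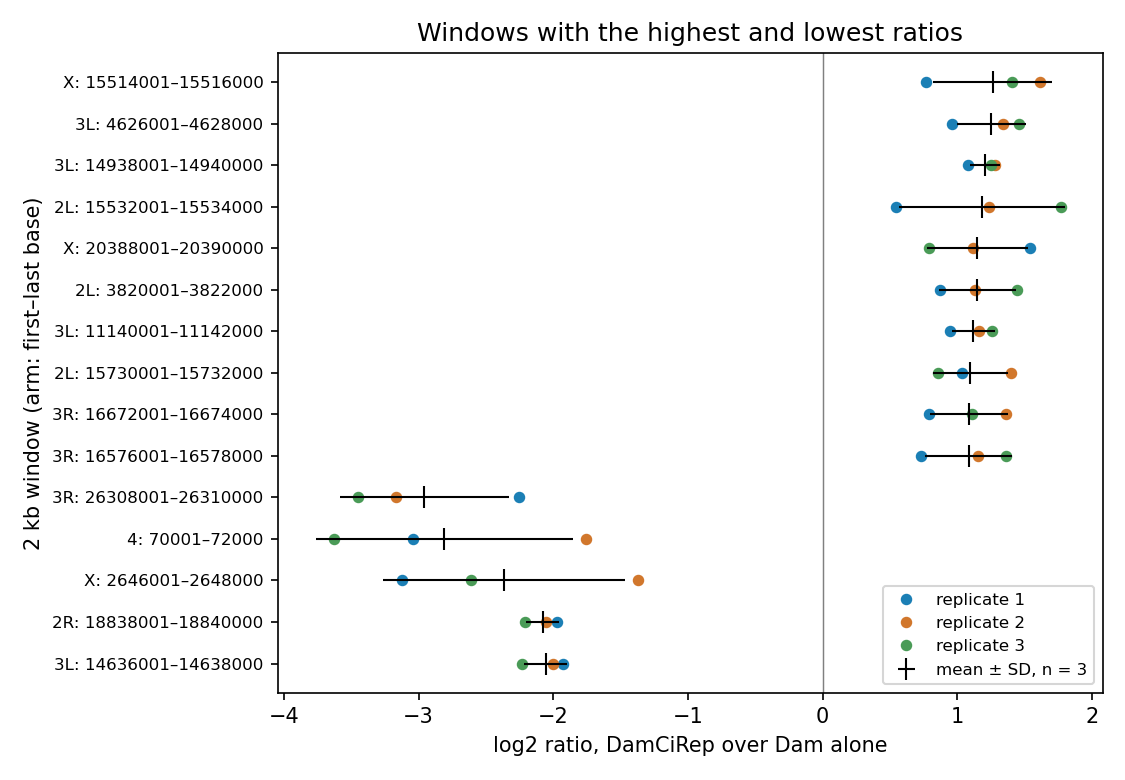
Log2 ratio of DamCiRep over Dam alone (horizontal axis) in the 10 highest and 5 lowest 2 kb windows (vertical axis), with 1 point per replicate and a black bar for the mean ± SD (n = 3). The highest windows lie between 1.08 and 1.26 and the lowest between -2.96 and -2.06.

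Called windows lay next to each other more often than shuffled calls did. The 5493 higher windows formed 3943 runs of adjacent windows, against a mean of 4969 in 100 shuffles of the calls, and 319 runs held at least 3 windows, against 44.6. The 5195 lower windows formed 4114 runs, against 4727, with 186 of at least 3 windows, against 37.2. The longest run of higher windows covered 32 kb on X, from 292001 to 324000, with a mean ratio of 0.67 ± 0.23 (SD, n = 3). Runs of 22 kb lay on 2L from 15306001 to 15328000, with 0.64 ± 0.17, and on 3L from 8974001 to 8996000, with 0.62 ± 0.12 (SD, n = 3). A run of 20 kb on 2L from 7294001 to 7314000 had 0.59 ± 0.08 (SD, n = 3). The longest run of lower windows covered 20 kb on 2R, from 772001 to 792000, with -0.70 ± 0.07 (SD, n = 3). None of these runs contained one of the 5 lowest windows. Runs were chosen after their lengths were seen, and 100 shuffles gave no run longer than 14 kb on the higher and 12 kb on the lower side. The shuffles take windows as independent, and neighbouring windows are not. An excess over the shuffles therefore does not by itself show domains beyond that dependence.

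At the scale of 50 kb, an added comparison chosen after the data were seen, 352 of 2358 domains were higher with DamCiRep and 458 were lower by limma. The highest domain was on X from 250001 to 300000, with a ratio of 0.60 ± 0.24 (SD, n = 3), and it overlapped the longest run. Domains on 3L from 14900001 to 14950000 and on 3R from 17250001 to 17300000 followed, with 0.52 ± 0.26 and 0.48 ± 0.22 (SD, n = 3). The lowest domains were on 2R from 350001 to 400000, with -0.48 ± 0.05, and on 2L from 22350001 to 22400000, with -0.46 ± 0.05 (SD, n = 3). The first 50 kb of chromosome 4 had -0.42 ± 0.15 (SD, n = 3). Each fit with 1 replicate left out had 1 residual degree of freedom. Without replicate 2 limma called 0 higher and 0 lower, with 297 and 353 domains at an unadjusted p under 0.05. The named domains kept their sign on replicates 1 and 3, with 0.51 and 0.41 in the highest and -0.53 and -0.43 in the lowest. Others were nearer to 0 on replicate 3, with 0.32 and 0.27 in the named 3L and 3R domains. The first 50 kb of chromosome 4 had -0.25 there. Without replicate 1 limma called 223 and 266 domains, with 349 and 441 at an unadjusted p under 0.05. Without replicate 3 it called 403 and 540, with 480 and 646 unadjusted. The unadjusted counts differed less between these fits. The prior of limma also differed, with 4.59 degrees of freedom without replicate 2 and 65.7 without replicate 1. How far the calls depended on replicate 2 can therefore not be read from the counts alone. With the median-centred scanner signals of replicates 2 and 3 the split was 58.8% higher, against 43.5% in the main fit and 45.6% without replicate 1. All of this takes the directions as labelled, and an exchange of the DNA sources on all 3 arrays would make higher and lower domains change places.

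**Figure D2:**
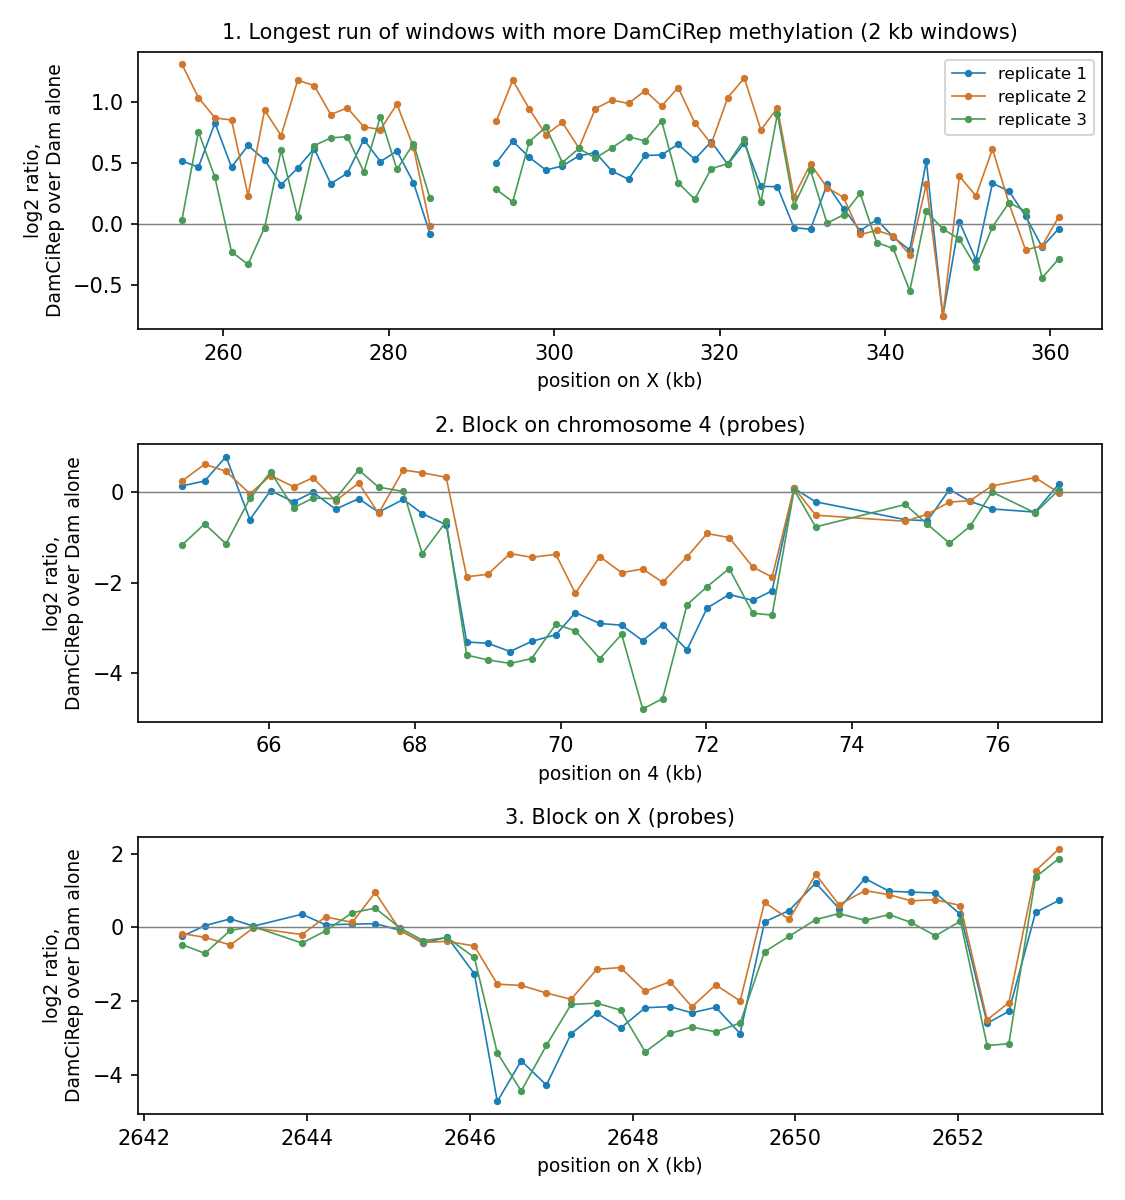
Log2 ratio of DamCiRep over Dam alone (vertical axis) by position in kb (horizontal axis), 1 line per replicate, over the longest run of higher windows on X (2 kb windows, with the line broken where windows had too few probes) and over blocks of single probes on chromosome 4 and X. The 3 replicates stay above 0 across the run from 292001 to 324000, and they drop together at the edges of both blocks. On replicate 2 the mean is -1.59 over the whole chromosome 4 block, from 68711 to 72963, and -1.64 over the X block. Beyond the X block the ratio falls again at the probe from 2652358, to -2.60, -2.51 and -3.21 on replicates 1, 2 and 3. At the next probe, from 2652625, it is -2.28, -2.04 and -3.16.

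Probe by probe, 8343 probes were higher and 13344 lower of 377566 tested with limma. With the directions as labelled, large ratios again lay on the Dam alone side: 1086 probes were more than 2-fold higher with DamCiRep on all 3 arrays and 4260 were more than 2-fold lower. Beyond 4-fold on all 3 arrays there were 2 probes with more DamCiRep methylation and 221 with less. Stretches of at least 5 neighbouring probes beyond 2-fold on every array numbered 2 on the higher side and 22 on the lower side. Both higher stretches lay inside a 1 Mb stretch of 2L that was tiled more densely, at 14462101 to 14462561 with a ratio of 2.02 ± 0.34 and at 14429422 to 14429771 with 1.58 ± 0.15 (SD, n = 3). At the ordinary spacing there were 0 higher and 18 lower stretches. With the DNA sources exchanged on all 3 arrays, the counts and shares of higher and lower probes would change places. The probe counts differed strongly when an array was left out. With replicates 1 and 2, whose Dam alone signals were nearly alike, averaged into 1, limma called 1 higher and 171 lower. The counts were 32 higher and 784 lower without replicate 1, and 0 and 0 without replicate 2, with 33507 and 35237 at an unadjusted p under 0.05 by limma. Without replicate 3 they were 20784 and 24857, and with a dye term, which takes 1 of the 2 residual degrees of freedom, 199 and 1715. Of the probe calls 38.5% were higher in the main fit and 3.92% without replicate 1, both with the authors' values and with loess on the scanner signals. With the scanner signals of replicates 2 and 3 centred on the median the share was 65.7%.

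The last comparison was between chromosome arms. With the directions as labelled, the X chromosome stood apart from the autosomes: 11.2% of its 10538 windows were called higher, against 9.34% elsewhere, and 4.42% lower, against 10.2% elsewhere. With the DNA sources exchanged on all 3 arrays, the shares of higher and lower windows would change places. By Fisher's exact test, adjusted over 12 tests of arms and directions, p was 1.23e-07 and 2.78e-89, but the test takes windows as independent and neighbouring windows are not. The mean ratio of X lay above that of the arms of chromosomes 2 and 3 by 0.09 ± 0.03 (SD, n = 3), with 0.11, 0.09 and 0.05 on replicates 1, 2 and 3. With the median-centred scanner signals of replicates 2 and 3 it was 0.0535, against 0.0734 for the authors' values of these arrays. Over the 3 arrays the two-sided exact sign-flip permutation p was 0.25, the smallest that 3 arrays can give. Windows called lower made up 10.0% to 10.4% of each arm of chromosomes 2 and 3, and 9.12% of all arms but chromosome 4, X included. Chromosome 4, which carries the ci gene itself, had 12.7% of its 589 windows called lower. Its mean ratio differed from chromosomes 2 and 3 by -0.04 ± 0.09 (SD, n = 3), within the spread of the arrays, and its sign on replicate 2, and over the median-centred scanner signals of replicates 2 and 3, was opposite (two-sided exact sign-flip permutation p = 0.5).

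**Figure D3:**
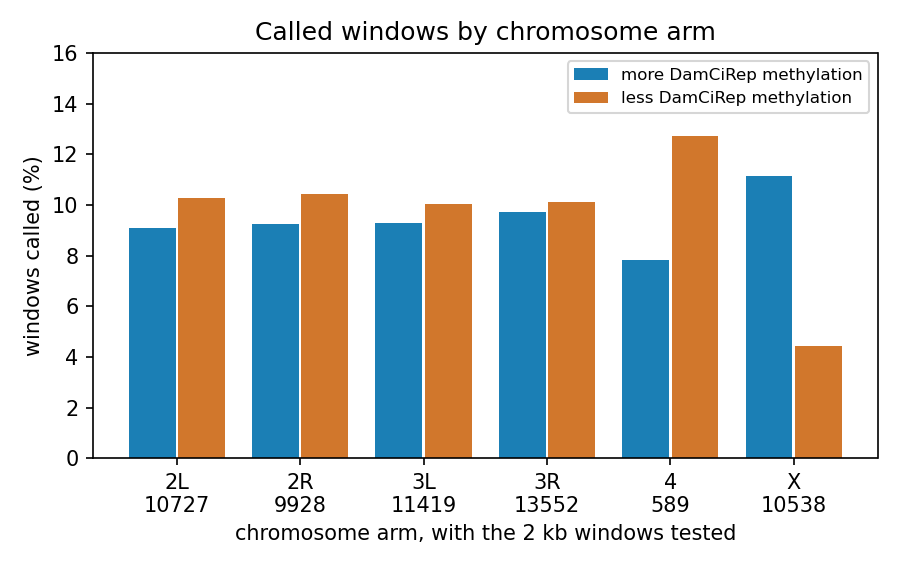
Percentage of tested 2 kb windows (vertical axis, from 0) called higher or lower with DamCiRep on each chromosome arm (horizontal axis, with the number of windows tested), with the directions as labelled. X has 4.42% of windows called lower, and the other arms have between 10.0% and 12.7%.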

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

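All tests in this part but that of the flanks were chosen after the values were seen. Scanner signals were not part of the main comparisons, and in 2 blocks the Dam alone signal stood far above the random control probes. It was 8.15 log2 units above them on chromosome 4 from 68711 to 71795, and 7.39 on X from 2646337 to 2649381. On chromosome 4 these signals were near the ceiling of the scans: the median probe of the block had 95.1%, 93.5% and 92.3% of the highest signal recorded on replicates 1, 2 and 3. In the X block it had 84.8%, 64.8% and 31.2%, with 6 of the 11 probes above 80% on at least 1 array. Probes near the ceiling make the sizes of the ratios uncertain. The DamCiRep signals of the blocks, 5.90 and 5.37 log2 units above the random probes, were also high. The mean ratios were -2.81 ± 1.01 and -2.49 ± 0.74 (SD, n = 3). The named 2 kb windows that overlap the blocks had -2.05 and -1.58 with the median-centred scanner signals of replicates 2 and 3. For the authors' values of these 2 arrays they had -2.69 and -1.99.

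Dye bias cannot give the blocks their sign, since they were lower on replicate 2 too, where the dyes were exchanged. The ratios there were -1.67 on chromosome 4 from 68711 to 71795 and -1.64 on X. Extra copies of these sequences in the Dam alone embryos, such as those of a transgene construct, may give sharp edges, and so may the ends of GATC fragments. The lowest mean within 1 kb of a block was -1.92, on the right of the chromosome 4 block. By the bound fixed beforehand, a flank more than 2-fold lower was to count against extra copies, and this flank passed it. It was set aside only after its value was seen, because the block was bounded by a 2-fold limit on every array. Another 4 probes carried the block to 72963, after which the next probe had 0.08. On the left of the X block the mean was -0.52, just outside the range that extra copies were to give. With its bound changed afterwards, the test cannot decide about extra copies. Beyond the X block the ratio fell again at the probes from 2652358 and 2652625, with ratios above 0 at the probes on either side. What this interruption means was not tested. An exchange of the DNA sources in the labels of all 3 arrays would turn the -2.81 of the chromosome 4 block into an excess with DamCiRep. It cannot be told apart from the labelled direction, because all 3 arrays have 1 sign and the sequences of the constructs were not used here. The DamCiRep transgene carries ci coding sequence, and the ci gene lies on chromosome 4. Copies of that sequence in the DamCiRep embryos would give an excess with DamCiRep, the sign opposite to the labelled one. Whether the block lies in ci was not tested, since no annotation of the array's build was used. No biological explanation was tested.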

How the results depend on the processing

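Alternatives with scanner signals, averaged replicates 1 and 2, 50 kb domains, or without saturated probes, the densely tiled stretch or probes beyond 4-fold on all 3 arrays were chosen after seeing the data. All 15 named windows kept their direction and stayed below the adjusted p threshold under every alternative that kept 2 kb windows and gave them a value, 298 values over 20 alternatives, with sizes from 0.86 to 3.47. These windows were picked as the most extreme calls of the main fit, and several alternatives left their ratios unchanged. The 298 values are therefore not independent checks. The higher and lower window counts (5493 and 5195) moved by over 1.5 times under these: loess on the scanner signals of replicates 2 and 3, with or without Aquantile, which changes only mean intensity, 2834 and 2692 (3148 and 2997 for the authors' values of those arrays); an adjusted p of 0.01, 1148 and 1539; 5 kb windows, which are fewer, 2780 and 2847; combined probe p-values, 2672 and 1699. Medians of probes gave 3156 lower windows. Scanner signals of all 3 replicates, with the copied file, gave 12300 and 12049. Leaving out 1 replicate gave 1309 to 7453 higher and 1875 to 7061 lower windows. Probe counts (8343 and 13344) were 199 and 1715 with a dye term, which leaves 1 residual degree of freedom; at an unadjusted p under 0.05 they were 46648 and 46689, against 51345 and 50252. On scanner signals of replicates 2 and 3 they were 32 and 784 with loess, as with the authors' values without replicate 1, 2831 and 4848 with normexp, and 20340 higher when centred on the median. With replicates 1 and 2 averaged they were 1 and 171. Leaving out 1 replicate gave 0 to 20784 higher and 0 to 24857 lower probes. Lower 50 kb domains (458) were 300 with replicates 1 and 2 averaged and 303 with median-centred scanner signals. Leaving out 1 replicate gave 0 to 403 higher and 0 to 540 lower domains. Median-centred scanner signals raised the r of windows between replicates 2 and 3 from 0.53 to 0.65, and gave an X minus autosomes of 0.0535, against 0.0867 over 3 arrays and 0.0734 for the authors' values of replicates 2 and 3. Apart from fewer arrays or windows, the cause was not tested. The other window alternatives stayed within 1.5 times of the main counts. X minus autosomes was 0.07 to 0.10 with 1 replicate left out. Chromosome 4 minus autosomes (-0.04) was -0.09 to -0.01 with 1 replicate left out, and its sign turned, to 0.02, with median-centred scanner signals, all within 1 SD of the arrays. Runs joined across 1 window numbered 3410 and 3622. Tests of genes, gene lists, ci exons and the Ci motif were not run. Probes near the level of the random probes, 15.1% to 26.9% per scan, limit the ratios there.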

Other observations

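The tests of the normalization, the background correction and the brighter probes were fixed before their results were seen, and the others in this part were chosen after. With the directions as labelled, the 1 Mb nearest the centromere of 2R had a ratio that differed from the rest of the arm by -0.24 ± 0.06 (SD, n = 3). Of its windows 31.2% were called lower and 3.12% higher. On 3L the difference was -0.17 ± 0.07 and on X -0.06 ± 0.02 (SD, n = 3). On 3R it was 0.08 ± 0.05, in the other direction, and on 2L 0.02 ± 0.08. An exchange of the DNA sources on all 3 arrays would turn these signs and shares round. The ratios of neighbouring places were shared between arrays over short distances: r between replicates 1 and 2 was 0.59 at the same probe, 0.34 at 0.3 kb, 0.10 at 2.1 kb and 0.06 at 10.2 kb. At the same distances it was 0.43, 0.24, 0.05 and 0.03 between replicates 1 and 3, and 0.43, 0.26, 0.06 and 0.04 between replicates 2 and 3.

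With the directions as labelled, probes with large ratios lay on the Dam alone side, 221 against 2 beyond 4-fold on all 3 arrays. The authors' normalization does not account for this. Counting probes beyond 4-fold on replicates 2 and 3 only, the Dam alone side held 28.7 times as many in the authors' values. In the median-centred scanner ratios of these arrays it held 29.3 times as many. A weaker signal over background with DamCiRep does not account for all of it, since the excess on these arrays was lower but still 16.9 times after normexp correction. Loss of whole fragments from the DamCiRep embryos would leave their signal at background, and only 9.95% of the 221 probes were below the 95th percentile of the random probes there. With the DNA sources exchanged on all 3 arrays, the same values would describe Dam alone in place of DamCiRep. A change in how far Dam reaches these sites when fused stays open as a hypothesis and was not tested.

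Replicates 1 and 2 were closer to each other than to replicate 3. Their Dam alone signals correlated at r = 0.992 across probes, above the 0.944 and 0.946 with replicate 3 and above the 0.976 of DamCiRep between replicates 2 and 3. This is consistent with 1 Dam alone DNA on both arrays, and a shared day of preparation stays open. A higher background on replicate 3 was to leave almost no gap in r among the probes brighter than the median. The gap there was still 0.0805. Taking only brighter probes narrows the range and lowered every r, to 0.982 for Dam alone between replicates 1 and 2 and 0.959 for DamCiRep. That alone can widen a gap, so the test does not exclude a higher background. The DamCiRep level rebuilt from Dam alone and the ratio had r = 0.964 between replicates 1 and 2, 0.960 between 1 and 3 and 0.964 between 2 and 3. The rebuilt level lacks the intensity trend that the authors' values leave out, and for replicates 2 and 3 its r was below the 0.976 of the scans. Replicate 1 had no usable DamCiRep scan. Whether the likeness of replicates 1 and 2 extended to DamCiRep can therefore not be told. If the arrays share Dam alone DNA, their spread is too small: with both averaged, limma called 4199 higher and 3962 lower windows, 241 and 300 domains of 50 kb, and 1 and 171 probes.

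The 3 arrays allow 4 patterns of sign, taking a pattern and its opposite as 1, too few for a share under 0.05. In 1 of the 4, the labelled one, limma called 10688 windows, and the highest of the others called 0, with 835 at an unadjusted p under 0.05. For probes the labelled pattern called 21687 and the highest other 0, with 9560 unadjusted, and for 50 kb domains 810 and 0, with 33 unadjusted. The pattern that follows the dyes called 0 windows by limma, with 155 unadjusted.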
